A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

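RNA of 2 fission yeast (Schizosaccharomyces pombe) mutants was compared with wild-type RNA on 2 two-colour Agilent tiling arrays. One array held asf1-1 RNA and the other RNA of the hip1 deletion, each in the red channel (Cy5), with wild-type RNA in the green channel (Cy3). Per the labels' protocols, cultures grew exponentially at 30 °C in rich medium, ribosomal RNA was depleted, and cDNA was labelled indirectly after reverse transcription. There was 1 array per mutant and no dye swap, so no test was run and no p-value is given. Whether both arrays carried the same wild-type extract is not given in the sources used here, and any dye bias has the same sign on both arrays.

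Per the file headers, the authors' spot intensity values came from Agilent Feature Extraction 10.1.1.1. The deposited median intensity of each spot and of its local background is not normalized. The deposited log10 ratio and the processed intensity values are background-subtracted and dye-normalized, per the file headers. The log10 ratio equalled the log10 of the ratio of the processed signals within 0.001 on 96.1% of asf1-1 and 94.3% of hip1 deletion probes. The deposited p-value of each log ratio comes from the scanner software and describes 1 spot, not replicates. The authors' series table holds log2 values equal to the scanner log ratio, set to 0 where that p-value was above 0.05, which held for 36.1% of asf1-1 and 43.1% of hip1 deletion probes. Its scale and direction were settled by this match, which leaves no room for centring beyond that of the scanner log ratio. Without the zeros its column medians were -0.456 in asf1-1 and -0.473 in the hip1 deletion.

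The design had fixed the mean spot signal, and the median signal was used in its place. Median signals were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and log2 red over green was normalized by loess within each array, with control spots and outlier spots at weight 0. There were 43993 probes and 1227 control spots, and 850 probes were outliers on at least 1 array and were left out. Probes were used when well above background in at least 1 of the 4 channels. The share of probes well above background was 79.6% in the green and 93.9% in the red channel of the asf1-1 array, and 78.9% and 88.8% on the hip1 deletion array. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

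Before the data were examined, the plan was to summarise probes by annotated gene, to use fixed gene lists, and to compare sense with antisense, gene ends, intergenic probes and named heterochromatic regions. None of these is reported. The array files give probe positions and strands but pair no probe with a gene, and the build of those positions is not given in the sources used here. The gene table supplied for names is of assembly ASM294v3, and no source used here says whether the array positions are of that build. A match of that table to the array was tried, by estimating an offset in each stretch of chromosome from the wild-type signal. An estimated offset amounts to converting positions between builds, so it was withdrawn, and no gene name, list or strand call made from it is used here. Its results had been seen before the unit below was chosen. For the same reason the probes of hip1 itself could not be used to check the array labels, and the fixed rule for named genes was applied to windows.

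Ratios were summarised as the median over probes of 1 strand in fixed windows of 1 kb, with at least 3 probes. This unit was chosen after seeing the data. Windows at or past 2-fold were counted. Per array the 12 highest and 12 lowest windows with at least 5 probes, and at least 80% of probes on the side of the window value, are eligible to be named, as are the 8 windows with the largest difference between mutants in each direction. The SD given with a window is over its probes and covers spot differences only. For single channels, the loess ratio was recombined with the mean log2 intensity after quantile normalization of that intensity between the arrays. The strand choice, the crossed ratios, the wild-type signals and the correlations of channels rest on these values. Where both strands of a window were measured, the strand at least 2-fold dimmer in the wild-type channel of the other array was called the dimmer strand. Tiled blocks were compared with 10000 draws of runs of as many neighbouring probes in the long block, matched on mean intensity, and no percentile is given where the block's intensity lay outside that of the runs. The alternatives were no background subtraction, the scanner log ratio, the series table, median centring, no or a stricter filter on dim probes, the mean, at least 8 probes, alternate probes, a 1.5-fold threshold and crossed wild-type channels. Loess on probes above background in all 4 channels, 2-kb windows and the strand chosen from all 4 channels were added after seeing the data.

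The steps were tested on a simulated array of 4380 windows, 200 of them changed. Of 50 windows changed 4-fold, 86% were called in the right direction, and of 50 changed 2-fold 34% were called, with a median recovered log2 ratio of 0.90. None of the 4180 unchanged windows was called. The simulated noise was independent between probes and its size was not taken from the measured probe scatter. These shares therefore do not give the rate of false or missed calls on the 2 arrays. The number of arrays limits the precision of every value.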

Results

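The expression of 2 histone chaperone mutants of fission yeast was measured against wild type on 2 tiling arrays, 1 for asf1-1 and 1 for the hip1 deletion. Asf1 is a histone H3-H4 chaperone, and Hip1 is a subunit of the HIRA chaperone complex. The series title places the measurement in a study of histone deacetylation and nucleosome occupancy at heterochromatic loci. The arrays carried 43993 probes of 60 bases on alternate strands every 50 bp. Most of them (40975) tile chromosome 2 from 1000011 to 3049820, and smaller blocks lie on chromosomes 1, 2 and 3 and on a sequence that the files number 4. Positions are those of the array files, whose build is not given. The files pair no probe with a gene, so loci are given by position and strand, and all values rest on 1 array per mutant without replicates.

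In asf1-1, RNA from 2 short loci on chromosome 2 stood far above wild type. On the minus strand between 1814011 and 1818970, 5 consecutive windows had a median log2 ratio of 5.81, and on the plus strand between 1966061 and 1972020, 6 windows had a median of 5.64. A window on the minus strand of chromosome 3 at 14011 to 14970 followed with 4.97 ± 2.23 and a window on the minus strand of chromosome 2 at 2573011 to 2573970 with 4.87 ± 0.77 (SD over 10 probes). Probe sequences were not analysed here, so signal from similar sequences elsewhere in the genome cannot be excluded at any locus. Of 4380 windows measured, 593 were at least 2-fold higher and 333 at least 2-fold lower than wild type. All counts are relative to the middle of each array, which loess and median centring set near 0. An overall rise or fall of RNA in a mutant would be removed. Before normalization the median log2 ratio over probes was 0.84 in asf1-1 and 0.14 in the hip1 deletion, which dye alone may give. The lowest window, on the plus strand of chromosome 2 at 4530101 to 4530960, had a log2 ratio of -2.94 ± 0.44 (SD over 9 probes). The minus-strand window at 2601011 to 2601970 had -2.49 ± 0.27 (SD over 10 probes). The number of windows past 2-fold depends on the scaling: median centring gave 1182 higher and 857 lower, and loess on the bright probes gave 1006 and 258.

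The same 2 loci on chromosome 2 led the hip1 deletion array. The minus-strand locus from 1814011 had a median log2 ratio of 5.52, the plus-strand locus from 1966061 had 5.44, and the window at 2573011 to 2573970 had 5.30 ± 0.59 (SD over 10 probes), while the chromosome 3 window at 14011 had -0.08 ± 0.54. There were 554 windows at least 2-fold higher and 161 at least 2-fold lower. The lowest window, on the plus strand at 2603061 to 2603920, had -2.45 ± 1.1 (SD over 9 probes), and had -2.52 ± 1.05 in asf1-1. Counting a lone window as a run, the higher windows formed 364 runs in the hip1 deletion and 375 in asf1-1. Of these, 231 and 234 were lone windows, and 35 and 46 held 3 or more. The longest runs held 6 windows on both arrays. Median centring gave 880 higher and 414 lower windows, and the scanner log ratio gave 838 and 499.

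**Figure D1:**
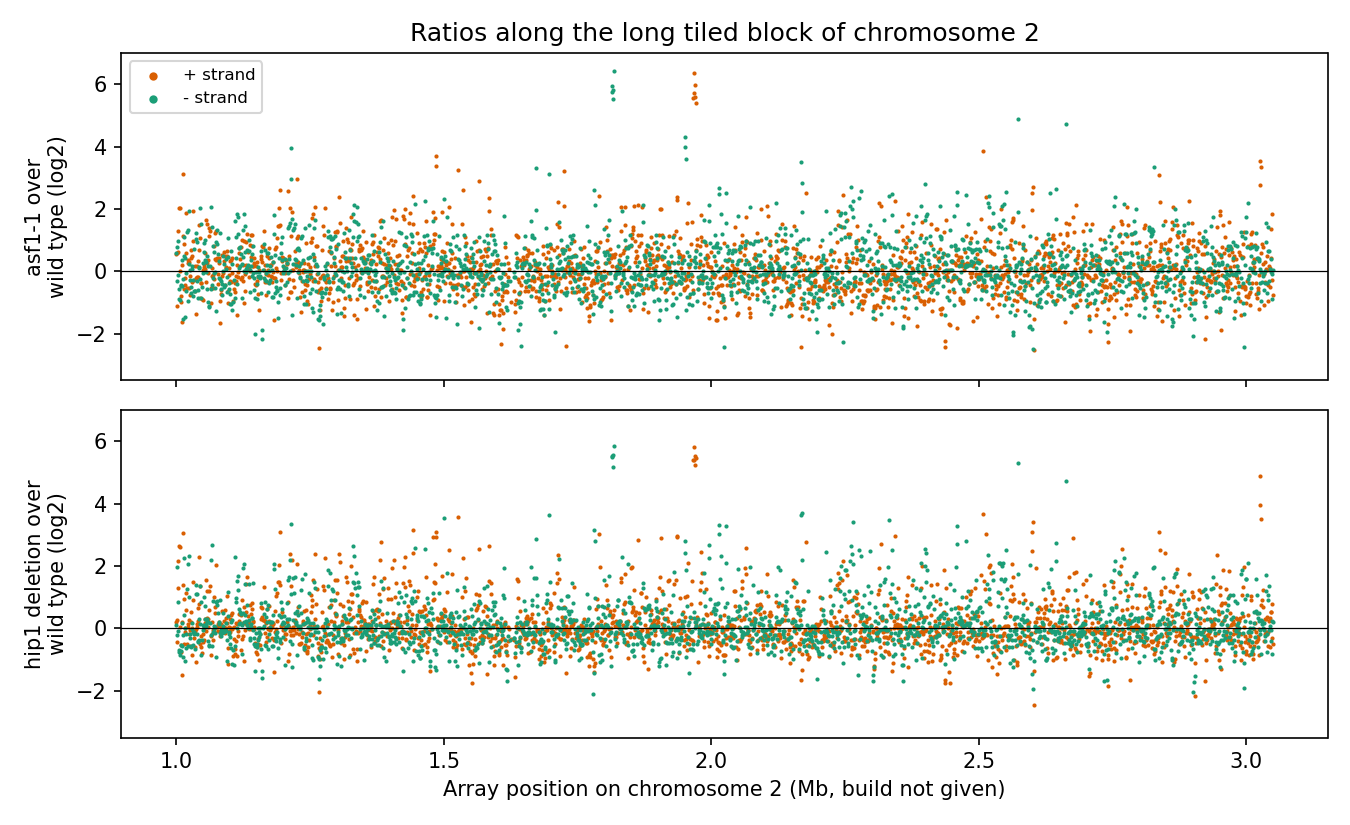
Log2 ratio of mutant over wild type in 1-kb windows along the long block of chromosome 2, with array position in Mb on the x axis, asf1-1 above and the hip1 deletion below, and each point 1 window coloured by strand. The groups of points above 5 are the minus-strand locus from 1814011 and the plus-strand locus from 1966061, with a single window at 2573011 that reached 5.30 in the hip1 deletion.

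The ratios of the mutants were alike across windows. Pearson's r was 0.87 and Spearman's rho 0.87 over 4380 windows, which are not independent replicates. In both mutants 434 windows were at least 2-fold higher, against 75.0 for independent lists, and 117 were lower, against 12.2. These counts depend on the scaling: they were 739 and 350 with the scanner log ratio, 678 and 336 with the series table, and 836 and 367 with median centring. A simulation of unchanged mutants gave them and 1 shared wild-type extract noise of equal variance, set from the hip1 deletion array. It gave r = 0.50, with 178 windows higher and 177 lower in both, and a covariance of 0.35 against 0.68 observed. The equal variances fix that r and covariance beforehand. A wild-type extract that deviates more than the mutants would give a higher r, so the simulation does not bound what a shared extract explains. With the wild-type channels crossed between arrays, r was 0.79. Part or all of the likeness may come from wild-type RNA and dyes common to both ratios, which 1 array per mutant cannot separate.

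The 8 windows with the largest excess in asf1-1 over the hip1 deletion all lay on the first block of chromosome 3, and 4 of the 8 with the largest deficit lay on the plus strand of the second block of chromosome 2. On the plus strand of chromosome 3 at 4061 to 5020, the log2 ratio was 4.69 ± 1.53 in asf1-1 and -0.96 ± 0.32 in the hip1 deletion (SD over 10 probes). At 14061 to 15020 it was 4.59 ± 1.80 and -0.81 ± 0.74. On the plus strand of chromosome 2 the window at 4530101 was -2.94 in asf1-1 and 0.28 ± 0.09 in the hip1 deletion. The hip1 deletion value has no settled sign, as it was 0 with the series table and -0.333 with median centring. Near 1.6 Mb of chromosome 2, the plus-strand window at 1606061 to 1607020 had -2.34 ± 0.32 in asf1-1 and -0.60 ± 0.20 in the hip1 deletion, but with crossed wild-type channels the order reversed to -1.19 and -1.69. The minus-strand window at 1644011 reversed likewise, from -2.40 and -0.63 to -1.31 and -1.75, so neither difference between the mutants is settled. In all, 64 windows were at least 2-fold higher in asf1-1 than in the hip1 deletion and 65 at least 2-fold lower. These counts depend on the processing: they were 210 and 69 with the scanner log ratio, 219 and 103 with the series table, 120 and 54 with median centring, and 200 and 124 with crossed wild-type channels.

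**Figure D2:**
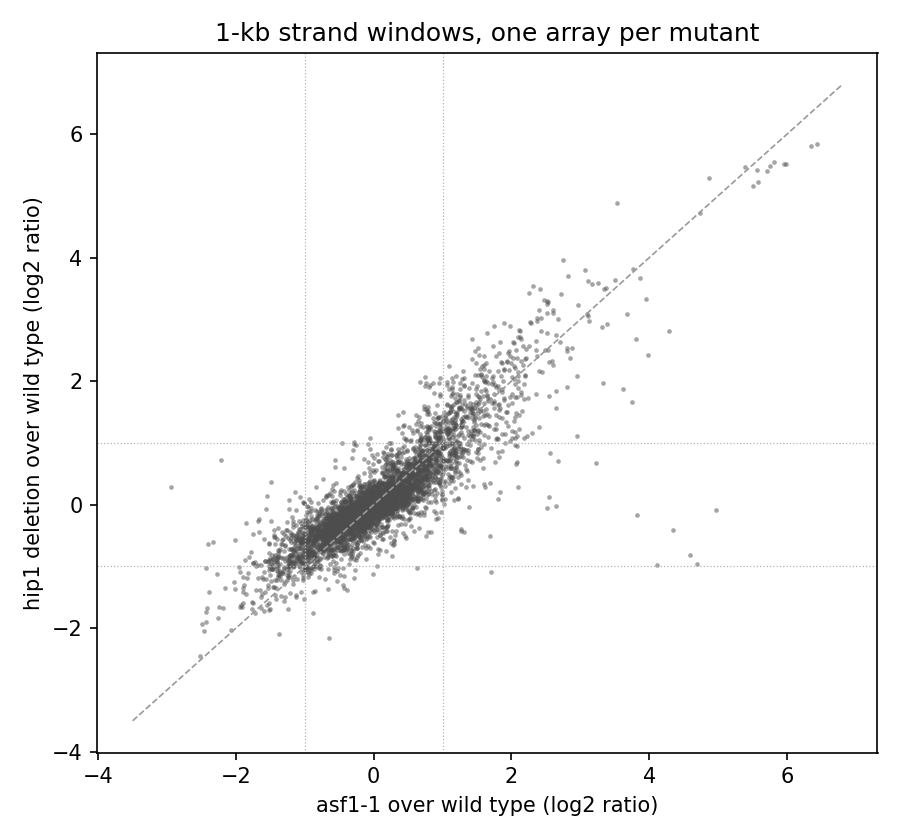
Log2 ratio over wild type of each 1-kb window in asf1-1 (x axis) and in the hip1 deletion (y axis), with dotted lines at 2-fold and a dashed line of equal values. Most windows lie near the dashed line (r = 0.87), and a few reach up to 4.97 in asf1-1 while near or below 0 in the hip1 deletion.

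**Figure D3:**
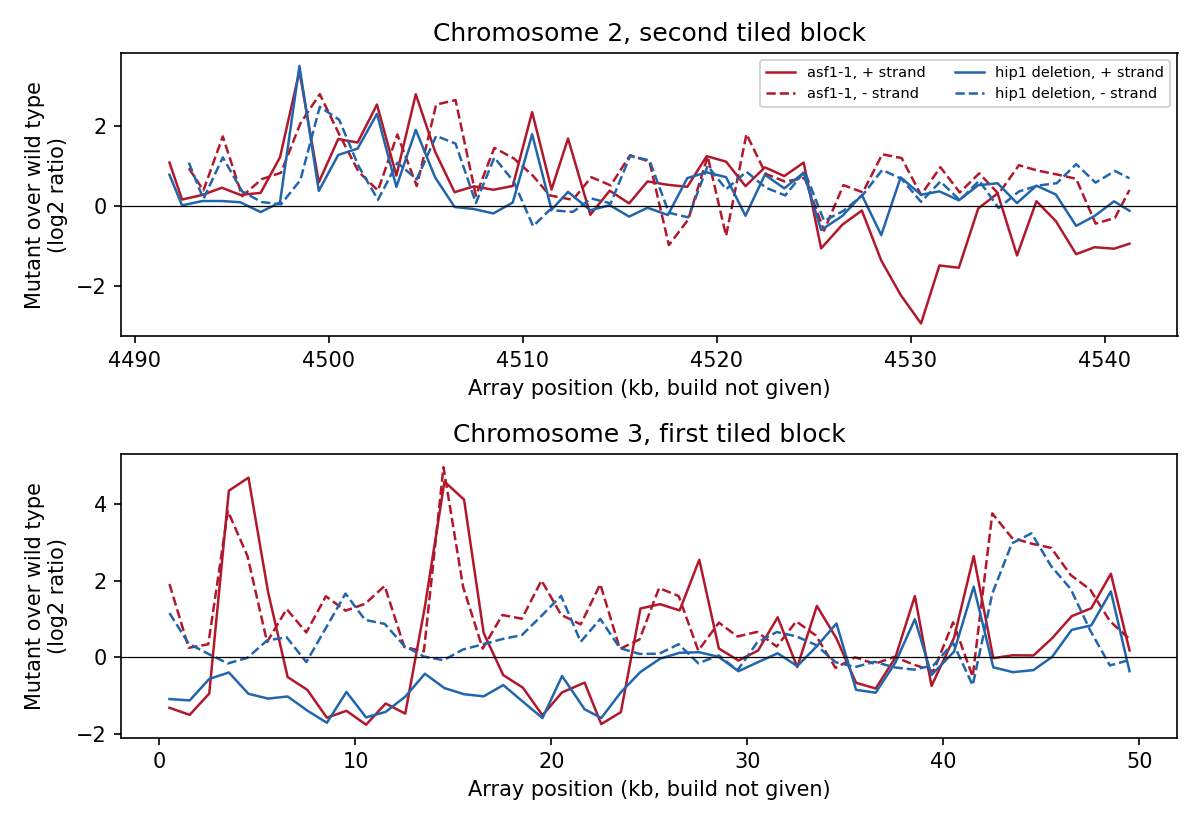
Log2 ratio over wild type along the second block of chromosome 2 and the first block of chromosome 3, by array position in kb, with asf1-1 in red, the hip1 deletion in blue, the plus strand solid and the minus strand dashed. The asf1-1 plus strand reaches -2.94 on chromosome 2 and 4.69 on chromosome 3, the minus strand 4.97, where the hip1 deletion does not follow.

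Without gene annotation, strands were compared by their wild-type signal. The dimmer strand had higher mutant over wild-type ratios than the brighter strand on both arrays. In asf1-1 the median log2 ratio was 0.42 on the dimmer and -0.23 on the brighter strand of 1838 windows, and the dimmer strand was the higher one in 73.4%. In the hip1 deletion the medians were 0.31 and -0.15 over 1857 windows, with 71.8%. On the dimmer strand 433 windows were at least 2-fold higher and 58 lower in asf1-1, and 452 and 42 in the hip1 deletion. On the brighter strand the counts were 89 and 209 in asf1-1 and 60 and 84 in the hip1 deletion. The dimmer-strand counts depend on the scaling: median centring gave 994 and 15 in asf1-1 and 764 and 14 in the hip1 deletion, and the scanner log ratio gave 791 and 127, and 718 and 162. The strand was chosen by wild-type signal, and each ratio also divides by wild-type signal. If both arrays carried the same extract, its deviations would enter both and raise the dimmer strand's ratios without a change in the mutants. Whether the dimmer strand is antisense to a gene was not analysed here.

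Outside the long block, the block of chromosome 1 from 2195400 to 2200359 had opposite strands apart. Its minus strand had a median log2 ratio of 1.83 in asf1-1 and 2.28 in the hip1 deletion, against -0.70 and -0.53 on the plus strand. Over both strands its median lay at percentile 96.1 in asf1-1 and 97.8 in the hip1 deletion among runs of the long block matched on intensity. The corresponding percentiles were 99.9 and 92.4 for the block of chromosome 3 from 1724400, 98.2 and 94.9 for that from 1838900, and 52.7 and 75.9 for the sequence numbered 4. For the sequence numbered 4 the match was loose: its mean log2 intensity was 8.97, and the runs spanned 8.74 to 9.98. Percentiles were not recomputed under the other scalings. The plus strand of chromosome 3 from 1838900 to 1840859 had 2.51 in asf1-1 and 3.25 in the hip1 deletion, against 0.22 and -0.22 on the minus strand. In the block from 1724400 the plus strand had 2.78 and 1.24, against 0.71 and -0.09 on the minus strand. The percentiles of these blocks therefore mix strands that lie apart. On the minus strand of chromosome 3, the 6 windows from 42011 to 47970 had a median of 2.91 in asf1-1 and 2.08 in the hip1 deletion. The interval of chromosome 2 from 1600001 to 1650000 was dim, with 55.0% of probes above background in all 4 channels. Its median was -0.38 in asf1-1 and -0.19 in the hip1 deletion, and turned to 0.17 and 0.20 with median centring, so it has no settled direction.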

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

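The tests of intensity, of the strand choice, of the covariance and of the wild-type extract were chosen after the results had been seen. With loess within each array, 1 window moved at least 2-fold in opposite directions in the mutants, on the plus strand of chromosome 3 from 5061 to 6020. Its log2 ratio was 1.70 ± 1.05 in asf1-1 and -1.09 ± 0.52 in the hip1 deletion (SD over 10 probes). The difference of 2.79 was not tested. The wild-type log2 signal there was 9.70 on the asf1-1 array and 8.43 on the hip1 deletion array, so the size of either ratio is not settled. With the scanner log ratio, the plus-strand window at 4061 was opposite too, at 4.58 in asf1-1 and -1.36 in the hip1 deletion. So were those at 14061 (4.69 and -1.19) and 15061 (3.98 and -1.44). In the hip1 deletion, however, the values at 4061, 14061 and 15061 are not settled past 2-fold. They were -0.322, -0.482 and -0.503 with crossed wild-type channels, and -1.21, -0.0566 and -1.29 with median centring.

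The dimmer strand had higher ratios than the brighter strand, by a median of 0.632 in asf1-1 and 0.502 in the hip1 deletion (log2). With the strand chosen from all 4 channels the difference was 0.567 and 0.430. Those channels include both wild-type channels, so a deviation of a wild-type extract common to the arrays would still enter the choice and the ratios. A noisy wild-type signal in the choice is therefore not excluded. Dye bias that follows intensity stays open: loess left 0.632 and 0.502 of the 2.02 and 1.44 found with median centring, and the difference at matched intensity, 1.40 and 1.07, decides nothing, since a lower wild-type signal at equal mean intensity is a higher ratio. More second-strand cDNA in the mutant labelling stays open too: the SD of the strand difference over windows was 3.37 and 3.71 times that expected from probe scatter, past the bound set beforehand, but that bound was wrong because changes that differ between windows raise the SD with or without a constant. Changed transcription of the dimmer strand may also contribute, and 1 array per mutant does not separate these.

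The window ratios of the mutants were alike. Dye bias of single probes can add no more covariance than the probe scatter within windows allows, and the observed covariance was 9.69 times that, which argues against it as the whole cause; bias common to neighbouring probes was not tested. The variance of window ratios was 10 and 12.3 times that expected from probe scatter in asf1-1 and the hip1 deletion, which real changes raise as well. A wild-type extract unlike a typical one may still lie behind the likeness. The wild-type channels correlated at 0.994 across windows, but the channels of the different mutants correlated at 0.9785 too. The SD of the difference between arrays was 0.263 for the wild-type and 0.511 for the mutant channels. These values do not settle whether the extract was shared. No independent wild type was analysed here, so such an extract and a shared effect of the mutants cannot be told apart.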

How the results depend on the processing

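Loess on the bright probes, 2-kb windows and the strand chosen from all 4 channels were chosen after seeing the data. No paired analysis was possible because each mutant has 1 array. Alternatives limited to unique probe sequences or coding probes, and all those of gene lists, named regions and named genes, were not run because genes and probe sequences were not analysed here. Counts were taken as moved past 1.5 times, medians past 0.25 (log2) and r past 0.1. Pearson's r stayed between 0.787 and 0.926 under the alternatives run, and the dimmer minus brighter difference stayed above 0 on both arrays. Of 1048 values of the 44 windows eligible to be named, 941 moved by less than the SD over probes and 107 moved by more. Of those past 2-fold with loess within each array, 0 changed sign. Changes of sign were not counted for windows under 2-fold, and some occurred there. The first count overstates stability. Some alternatives leave the probes of a window as they were, and a large SD lets a large move pass. Loess on the bright probes moved the median of all windows by 0.22 in asf1-1 and 0.16 in the hip1 deletion. The share of higher calls, 64.0% in asf1-1 and 77.5% in the hip1 deletion, lay between 55.9% and 79.6% in asf1-1 and between 62.05% and 85.8% in the hip1 deletion under the alternatives. The causes of the changes below were not tested. Probes that are dim in 1 channel limit the ratios, and 55.0% of probes from 1600001 to 1650000 of chromosome 2 were above background in all 4 channels.

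The scanner log ratio gave 996 higher and 585 lower windows in asf1-1 and 838 and 499 in the hip1 deletion, with 739 higher and 350 lower in both and 210 higher in asf1-1 than in the hip1 deletion. On the dimmer strand it gave 791 higher and 127 lower in asf1-1, 718 and 162 in the hip1 deletion, and strand differences of 1.11 and 0.859. The series table gave 911 and 568 windows in asf1-1, 474 lower in the hip1 deletion, 678 higher and 336 lower in both, and 219 higher and 103 lower in asf1-1 than in the hip1 deletion. On the dimmer strand it gave 728 and 117 in asf1-1, 145 lower in the hip1 deletion, and a strand difference of 0.979 in asf1-1. Median centring gave 1182 and 857 windows in asf1-1, 880 and 414 in the hip1 deletion, 836 and 367 in both, and 120 higher in asf1-1 than in the hip1 deletion. On the dimmer strand it gave 994 and 15 in asf1-1, 764 and 14 in the hip1 deletion, and strand differences of 2.02 and 1.44. Loess on the bright probes gave 1006 higher windows in asf1-1, 774 and 30 on its dimmer strand, 27 lower on that of the hip1 deletion, and strand differences of 1.00 and 0.79. At 1.5-fold there were 1083 and 854 windows in asf1-1, 926 and 551 in the hip1 deletion, 805 and 438 in both, and 227 higher and 322 lower in asf1-1 than in the hip1 deletion. The dimmer strand then had 768 and 179 in asf1-1 and 706 and 136 in the hip1 deletion. Only probes above background in all 4 channels gave 100 lower on the dimmer strand in asf1-1. The mean over probes gave 38 windows lower in asf1-1 than in the hip1 deletion, and crossed wild-type channels gave 200 higher and 124 lower.

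Block medians also moved. The second block of chromosome 2, from 4491601, had 0.54 in asf1-1 and 0.34 in the hip1 deletion. It had 1.07 and 0.636 with the scanner log ratio, 0.841 and 0 with the series table, 1.01 and 0.647 with median centring, and 1.07 and 0.688 with loess on the bright probes. The block of chromosome 3 from 1724400 had 1.23 and 0.46. In asf1-1 it had 1.66 with the scanner log ratio and the series table, 1.94 with median centring and 1.68 as a mean, and in the hip1 deletion 0 with the series table, 1.01 with median centring and 0.786 as a mean. The block from 1838900 had 0.97 and 0.67. In asf1-1 it had 0.714 with the scanner log ratio, 0.705 with the series table, 0.471 with median centring and 0.706 on even probes, and in the hip1 deletion 0.321 with median centring and 1.2 as a mean. The sequence numbered 4 had 0.05 and 0.03, against 0.353 in asf1-1 with median centring, and 0.513 and 0.351 with loess on the bright probes. The block of chromosome 1 had 0.73 in the hip1 deletion and 1.06 as a mean.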
